A study of Mus musculus with 4 samples.

How the data were processed

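ChIP-seq had been done on neural stem cells from E12.5 embryos of wild-type C57BL/6J mice, grown with 20 ng/ml EGF and 10 ng/ml FGF, per the labels' protocols. There were 4 samples in 4 groups of 1. They were a chromatin immunoprecipitation of the histone demethylase PHF2 (Cell Signaling antibody D45A2), its input, a chromatin immunoprecipitation of H3K9me2 (Abcam antibody ab1220), and its input. H3K9me2 is histone H3 dimethylated at lysine 9. The values came from 1 peak list for PHF2 and 1 for H3K9me2. The inputs and sequencing reads were not analysed here.

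The PHF2 peaks were called with MACS in Galaxy, per the file headers. The version, the control and the settings were not given in the sources used here. The submitters' processing notes list Bowtie2 and the mm10 genome. The caller of the H3K9me2 list was not given in the sources used here, and a p threshold appears only in the name under which that list was deposited, without the test it belongs to. The PHF2 list carries the authors' score, 1 deposited value per peak, whose scale was not given in the sources used here, so it served only to rank or filter peaks within that list. It ran from 100.02 to 3226, with no peak under 100.02. The score column of the deposited H3K9me2 list holds 0 throughout, so those regions were ranked by length. Lists of peaks give no read totals, and the depth of the samples is unknown. With 1 sample per group, no spread between cultures could be measured. All p-values describe these lists, and all intervals cover counting error only.

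The 5992 PHF2 peaks and 36111 of the 36171 H3K9me2 regions lay on chromosomes 1 to 19 and X and were analysed. The other 60 H3K9me2 regions lay on scaffolds. All coordinates are on mm10, printed 1-based. The reference was the GRCm38 genome, which is the mm10 assembly, with the GENCODE M21 annotation. A promoter was a window of 1000 bp on either side of a transcript start of a protein-coding gene. A gene with several starts had several windows, which were pooled per gene. This gave 21670 protein-coding genes and 29078 merged windows. A peak counted as lying at a feature when it overlapped it by 1 bp or more. CpG observed/expected and GC content were computed from the genome sequence of the windows.

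Shares of peaks at promoters, the overlap of both lists and the density of H3K9me2 by distance were set against 1000 random placements of the peaks, with their lengths kept, within their own chromosomes and outside assembly gaps of 50 bp or more. Classes of annotation came from peak centres and 100 placements. These permutation p-values were 2-sided, and the smallest they could reach was 0.002 with 1000 placements and 0.0198 with 100. Shares have 95% Wilson intervals. The promoters of PHF2 peaks and H3K9me2 regions were compared over genes with a 2-sided Fisher's exact test. An odds ratio had 0.5 added to each cell only where a cell was 0. Medians were compared with 100000 permutations, whose smallest p is 1e-05. Peaks per chromosome were compared with the number proportional to the length outside gaps, by an exact binomial test with exact intervals.

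There were 21 gene lists. Each was tested against all other protein-coding genes with a 2-sided Fisher's exact test and Benjamini-Hochberg adjustment over the 21 lists of a target, at an adjusted p of 0.05. Each list was also set against 10000 random lists matched on the decile of promoter CpG observed/expected. A total of 12 motifs were sought as consensus sequences on either strand in the central 200 bp of PHF2 peaks. The controls were windows of 200 bp at promoters without a PHF2 peak, matched on GC content in steps of 2 percentage points. Fisher's exact test was adjusted over the 12 motifs.

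The comparisons, tests, gene lists, motifs, most alternatives and the rule for named genes were chosen before the data were examined. For PHF2, the rule named the 15 genes with the highest-scoring promoter peaks and up to 4 genes of each list. For H3K9me2 it named the 10 genes with the longest promoter regions, up to 4 genes of each list and the 5 longest regions. It also named up to 10 genes with both, and Phf2, Ehmt1, Ehmt2, Kdm1a and E2f1. Not every gene that the rule named is reported here.

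The alternatives tried were promoter windows of 500 bp, 2 kb and 5 kb, the 5'-most start alone, all annotated genes, only the higher-ranked peaks, other definitions of overlap, other random placements, a Mantel-Haenszel odds ratio over 10 deciles of CpG observed/expected with 10000 permutations within deciles, and other motif windows and controls. Another 9 alternatives were added after the data had been seen. These combined the 5'-most start with CpG matching, used single windows in place of genes, with and without CpG deciles, left out X, counted genes that share an H3K9me2 region once, kept placements low in repeats, and matched motif controls on the number of CpG dinucleotides as well. The rule for cells of 0 was also chosen after the data had been seen. So was the choice to follow across alternatives only those lists and motifs that passed the threshold at least once. That left out 1 list for PHF2, 20 for H3K9me2 and 0 motifs.

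The procedures were tested on simulated data before use. Peaks placed at random gave a mean overlap ratio of 1.01 to random placement, with a p under 0.05 in 4 of 40 sets, and thinned overlaps gave 0.507. In sets of 21000 simulated genes, lists planted with 4-fold odds were called in 98.8% of cases and unchanged lists in 0.833%. An association made only through the CpG class used for stratification gave a crude odds ratio of 0.709 and a stratified one of 0.990. This simulation had no CpG differences within a class and no genes with several windows. The motif scan found 100% of planted copies of the consensus it searched for, which shows only that the search ran correctly. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9.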

Results

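PHF2 and H3K9me2 were mapped by ChIP-seq in mouse neural stem cells from E12.5 embryos. PHF2 is a histone demethylase with a PHD finger that binds H3K4me3, a mark of active promoters, and H3K9me2, a mark of silent chromatin, is described as its substrate. Each target had 1 ChIP sample and 1 input, without replicates. The values were positions of called peaks, and the depth of the samples is unknown. The PHF2 list held 5992 peaks with a median length of 1306 bp (459 to 6534 bp), which covered 0.333% of the genome. The H3K9me2 list held 36111 regions on the chromosomes analysed, which covered 0.120% of the genome. Of the 36171 regions listed, 20097 (55.6%) had the minimum length of 73 bp, and the longest had 367 bp.

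The first question was where PHF2 sits in the genome, and nearly all its peaks lay at promoters. Of the 5992 peaks, 5730 overlapped the promoter of a protein-coding gene, 95.6% (95% Wilson interval 95.1% to 96.1%). Random placement gave 4.34%, a ratio of 22.0 (permutation p = 0.002, the smallest possible). Peak centres lay at a median of 206 bp from the nearest start, 83.5% lay within 500 bp, and 77.1% lay downstream of the start. Only 171 peaks (2.85%) lay farther than 10 kb from a start. By centre, 2.20% of peaks fell in introns, where placement gave 37.2%, and 1.55% in intergenic DNA, where it gave 50.7%. PHF2 peaks marked 6306 of 21670 protein-coding genes (29.1%), and 750 peaks lay at promoters of 2 or more genes.

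The 15 genes with the highest-scoring PHF2 peaks included antagonists of growth factor signalling and transcription factors of neural progenitors, beside genes of other functions. The top score, 3226, belonged to a peak of 5400 bp at Spry2 (chromosome 14, 105892429 to 105897828), which encodes an antagonist of receptor tyrosine kinase signalling. A score of 3100 was shared by Spry4, a relative of Spry2, by Dusp6 (chromosome 10, 99262730 to 99268186), which encodes a phosphatase of ERK, and by Olig2 (chromosome 16, 91224338 to 91230537), which encodes a basic helix-loop-helix factor of progenitors and oligodendrocytes, so the order among these was not resolved. Myc, the growth regulator, had a score of 2571 (chromosome 15, 61984704 to 61988458). Sox4 (2931) and Sox11 (2369) encode transcription factors of neural differentiation. Marcks, Adgrl2, Zmiz1, Klf6, Ckb, Trib2, Irf2bpl and Bahcc1 completed the 15, with scores between 2356 and 2834. PHF2 had a peak at its own gene, Phf2 (score 188.5, chromosome 13, 48869826 to 48870825). Ehmt1, which encodes an H3K9 methyltransferase, had a peak with a score of 372 and Kdm1a, which encodes an H3K4 and H3K9 demethylase, a peak with a score of 197.6. E2f1, a driver of entry into S phase, had a weak peak (159.1). Ehmt2, which encodes the partner of the Ehmt1 product, had no PHF2 peak and no H3K9me2 region at its promoter.

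H3K9me2 regions lay mostly outside genes and avoided promoters. Only 515 of 36111 regions overlapped a promoter, 1.43% (95% Wilson interval 1.31% to 1.55%), against 2.62% by random placement, a ratio of 0.544 (permutation p = 0.002, the smallest possible). Intergenic DNA held 54.6% of region centres against 51.3% of placed ones, and introns held 35.0% against 36.8%. Coding exons held 0.781% against 1.16%. Each of these 3 differences had a permutation p of 0.0198, the smallest possible with 100 placements. The promoters of 498 protein-coding genes (2.30%) held a region. The longest promoter region, 260 bp, lay at Sfi1 (chromosome 11, 3193933 to 3194192), which encodes a centrosome protein and whose windows held 7 regions. Thtpa (197 bp), 4931408C20Rik (182 bp) and the olfactory receptor genes Olfr65 (178 bp), Olfr586 (166 bp) and Olfr1204 (160 bp) followed in the list of longest promoter regions, with 0610040J01Rik (178 bp), Fscb (158 bp), Clptm1l (157 bp) and Pgc (157 bp). The longest region of all had 367 bp and was intergenic (chromosome 4, 147609554 to 147609920). Of the 5 longest, 4 were intergenic and 1 lay in an intron of Klf12.

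Called PHF2 peaks and called H3K9me2 regions almost never coincided, the comparison that an enzyme and its substrate call for. The caller of the H3K9me2 regions was not given in the sources used here, a p threshold stands only in the name of the list, and most regions had the minimum length, so neither a called region nor its absence shows the mark with known certainty. Only 3 PHF2 peaks overlapped an H3K9me2 region, where random placement gave 134 (SD 11.8), a ratio of 0.0224 (exact binomial 95% interval 0.00462 to 0.0654, permutation p = 0.002, the smallest possible). When each peak kept its promoter or non-promoter class, placement gave 60.3 overlaps, a ratio of 0.0497 (permutation p = 0.002, the smallest possible). The 3 peaks, listed after their values were seen, lay at Hjurp, which encodes the chaperone of the centromeric histone CENP-A (chromosome 1, 88275615 to 88279796, with 2 regions), at Neurod1, which encodes a factor of neuronal differentiation (chromosome 2, 79457019 to 79458251), and 2692 bp from the start of 4931414P19Rik on chromosome 14. Around PHF2 peak centres, the share of bases under H3K9me2 regions was 0.0128 of the placed share within 0.5 kb and 0.225 of it from 0.5 to 1 kb. It was 0.609 of the placed share from 1 to 2 kb, 0.792 from 2 to 5 kb, 0.709 from 5 to 10 kb and 0.721 from 10 to 20 kb. From 20 to 50 kb it was 0.754, and from 50 to 100 kb it was 0.796 (permutation p = 0.002, the smallest possible, in each of these 8 classes). The placements were not matched on regional GC content or gene number. From the lowest to the highest of 4 GC classes of autosomal 1-Mb bins, H3K9me2 regions fell from 17.1 to 10.5 per Mb. PHF2 peaks rose from 0.376 to 4.85 per Mb. The deficit at larger distances was thus not told apart from the GC content of the surrounding DNA. Around the 262 PHF2 peaks away from promoters, the ratio within 0.5 kb was 0.0760 (permutation p = 0.04). In the classes between 0.5 and 5 kb around these peaks, the permutation p lay between 0.258 and 0.278, while the ratio was 0.597 from 5 to 10 kb (permutation p = 0.00999), 0.738 from 10 to 20 kb (permutation p = 0.034) and 0.824 from 20 to 50 kb (permutation p = 0.018). From 50 to 100 kb it was 0.996 (permutation p = 0.981).

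**Figure D1:**
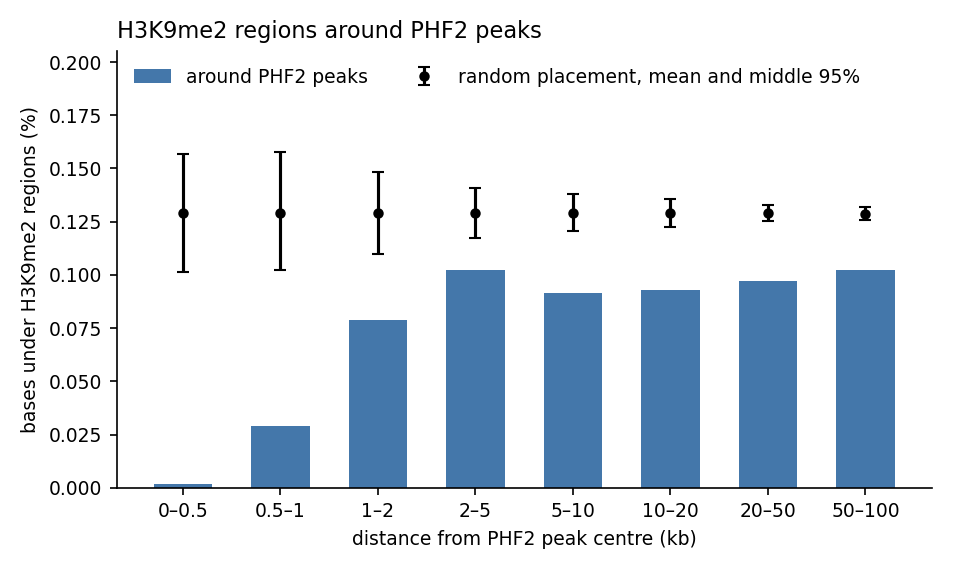
Share of bases under H3K9me2 regions (%) by distance from PHF2 peak centres (kb). Bars are the observed shares, and points with bars are the mean and the middle 95% of 1000 random placements. The observed share lay below the placed range in every class, by most within 0.5 kb, where the ratio was 0.0128. The placements were not matched on regional GC content.

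At the level of genes, promoters with a PHF2 peak carried H3K9me2 less often than other promoters, but not once CpG content was taken into account. Of 6306 genes with a PHF2 peak, 101 (1.60%) also had an H3K9me2 region in a promoter window, against 397 of 15364 other genes (2.58%), an odds ratio of 0.614 (95% interval 0.492 to 0.765, Fisher's exact p = 6.66e-06). Over deciles of CpG observed/expected the odds ratio was 1.67 (1.27 to 2.21, permutation p = 0.0008) for genes with all their windows pooled. It was 0.901 (0.558 to 1.46, permutation p = 0.758) with the 5'-most start alone, and 0.979 (0.643 to 1.49, permutation p = 0.998) for single windows. Genes with more windows had more DNA in which both could be found, and this was not adjusted for. The value of 1.67 was thus not told apart from an effect of pooling. With windows of 5 kb and without deciles, the odds ratio was 1.01 (Fisher's exact p = 0.804). The gene with both and the highest PHF2 score was Srgap2, which encodes a regulator of neuronal migration (score 1519), and its PHF2 peak, 131523057 to 131529590 on chromosome 1, and its H3K9me2 region, 131504308 to 131504380, lay apart. Tmem158, Usp1, Robo2, Bola1, Ncor1, Rfx3, Gprc5b, Slc25a25 and Pde10a came next, with scores from 571.6 to 1063.

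CpG-rich promoters had PHF2 peaks more often, and CpG-poor promoters had H3K9me2 regions more often, though few of either had the latter. The median CpG observed/expected was 0.622 at the 6306 promoters with a PHF2 peak and 0.319 at the 15364 without one, a difference of 0.303 (permutation p = 1e-05, the smallest possible). The median GC content was 52.7% with and 49.0% without a peak. From the lowest to the highest decile of CpG observed/expected, the share of genes with a PHF2 peak went from 0% to 73.1%, and the share with an H3K9me2 region went from 3.97% to 0.415%.

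**Figure D2:**
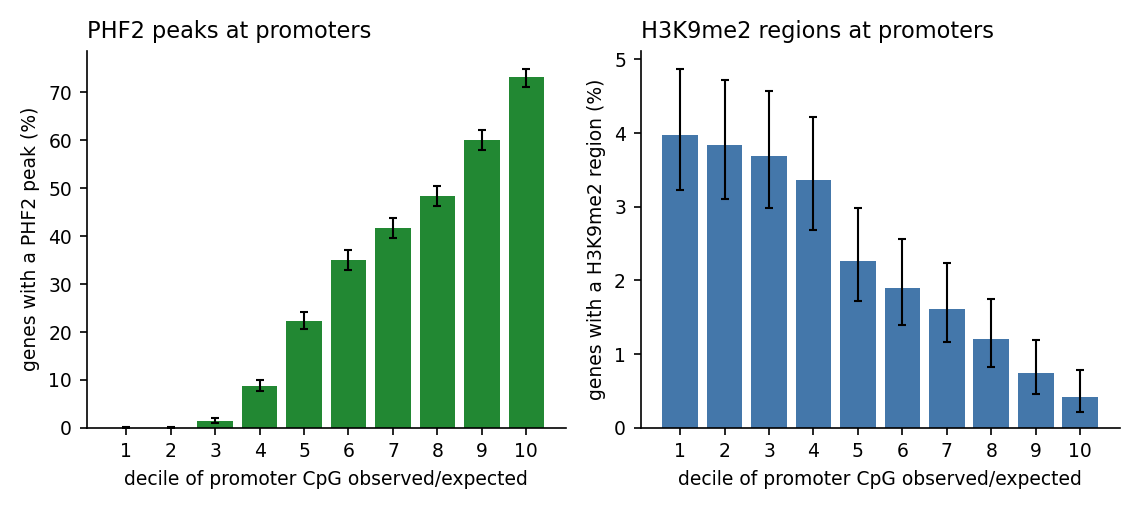
Share of protein-coding genes with a PHF2 peak (left, %) and with an H3K9me2 region (right, %) in the promoter window, by decile of CpG observed/expected, with 95% Wilson intervals. The shares ran in opposite directions, from 0% to 73.1% for PHF2 and from 3.97% to 0.415% for H3K9me2.

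PHF2 marked the promoters of many housekeeping, cell cycle and neural stem cell genes, and few or no Hox, germline and receptor genes, the last of which have CpG-poor promoters. Of the 21 lists, 12 held more genes with a PHF2 peak than the other genes and 7 held fewer, at an adjusted p of 0.05 in Fisher's exact test. The highest share was that of cytosolic ribosomal proteins, 74 of 80 genes (92.5%, odds ratio 30.4, 95% interval 13.2 to 69.9, Fisher's exact adjusted p = 4.42e-32), among them Rpl3, Rps12, Rpl13a and Rps2, but among the highest-scoring 10% of peaks the odds ratio was 2.29 (Fisher's exact adjusted p = 0.181). Neural stem cell genes followed with 20 of 23 (87.0%, odds ratio 16.3, 4.84 to 54.8, Fisher's exact adjusted p = 3.74e-08), and their highest scores were at the Notch effector Hes1 (2022), the glial and progenitor factor Sox9 (1839), and the intermediate filament genes Vim (1758) and Nes (1694). RNA splicing genes had 53 of 67 (79.1%), with Hnrnpa2b1 and Cbx3 on the same peak (score 1435). G1/S genes had 28 of 37 (75.7%), led by Myc, the cyclin genes Ccnd1 (1514) and Ccnd2 (1481), and the inhibitor gene Cdkn1b (900.3). G2/M and mitosis genes had 28 of 41 (68.3%), among them Wee1, Smc4, Mki67 and Cdk1. Genes of the H3K9 methylation machinery had 17 of 24 (70.8%), including Cbx3, Jmjd1c, Cbx5 and Ehmt1, but were not told apart from CpG-matched lists (mean 13.0, permutation adjusted p = 0.171).

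The other lists with more PHF2 peaks lay closer to the rate of all genes, 29.1%. DNA repair genes had 34 of 60 (56.7%), with H2afx, Lig3 and Topbp1 among those with the highest scores. Replication-dependent histone genes had 38 of 67 (56.7%), DNA replication genes 28 of 50 (56.0%, led by Rrm2, Orc4, Orc1 and Tyms), oxidative phosphorylation genes 45 of 81 (55.6%, led by Ndufv2 and Atp5b) and Notch signalling genes 16 of 29 (55.2%, led by Lfng, Hes1, Jag1 and Notch1). Histone genes can share a peak, as Hist1h1e and Hist1h2be did, so the test counts some peaks more than once. Among the higher-scoring 50% of peaks, the calls were lost for oxidative phosphorylation (odds ratio 1.31, Fisher's exact adjusted p = 0.383), DNA replication (1.44, 0.369) and repair genes (1.44, 0.347). Zinc finger genes had 132 of 391 (33.8%, odds ratio 1.25, 95% interval 1.01 to 1.54, Fisher's exact adjusted p = 0.0476), but this call was lost with windows of 500 bp, 2 kb or 5 kb and with the 5'-most start (Fisher's exact adjusted p from 0.05 to 0.0946), and among the higher-scoring 50% of peaks the odds ratio was 0.842. Neuronal genes (6 of 28, 21.4%, Fisher's exact adjusted p = 0.559) and glial genes (4 of 18, 22.2%, Fisher's exact adjusted p = 0.613) were not told apart from other genes. The neuronal genes with peaks included Gria2, Map2 and Neurod1, and the glial ones were Olig2, Olig1, Gja1 and Slc1a2.

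Among the lists with few PHF2 peaks, olfactory receptors had 0 of 1092, vomeronasal receptors 1 of 327 (Vmn1r4), and keratins and keratin-associated proteins 0 of 102. Germline genes had 0 of 26 and non-neural lineage genes 0 of 23. Hox genes, which pattern the body axis, had 1 of 39 (2.56%), and clustered protocadherins 1 of 57 (1.75%), Pcdhgc3. Against random lists of the same CpG content, ribosomal protein, splicing, neural stem cell, G1/S, G2/M, oxidative phosphorylation and zinc finger genes were still higher, 7 lists in all, and 6 lists were lower, olfactory receptors and keratins among them. Olfactory receptors had 0 against a matched mean of only 3.95, and vomeronasal receptors 1 against 0.702. DNA replication, repair, histone, Notch signalling, H3K9 methylation and non-neural lineage genes (0 against 1.89, permutation adjusted p = 0.277) were no longer told apart from the matched lists. Hox genes had 0.0543 and protocadherins 0.0512 of the matched number (permutation adjusted p = 0.00105 for each). Germline genes had 0 where matched lists had a mean of 9.50 (permutation adjusted p = 0.00105). Neuronal genes had 6 against a matched mean of 11.8 (permutation adjusted p = 0.0444). With the 5'-most start alone, the CpG-matched calls were lost for neuronal (permutation adjusted p = 0.187), olfactory receptor (0.139), keratin (0.234) and G1/S genes (0.127). Histone genes had 38 against 42.4 (permutation adjusted p = 0.343).

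**Figure D3:**
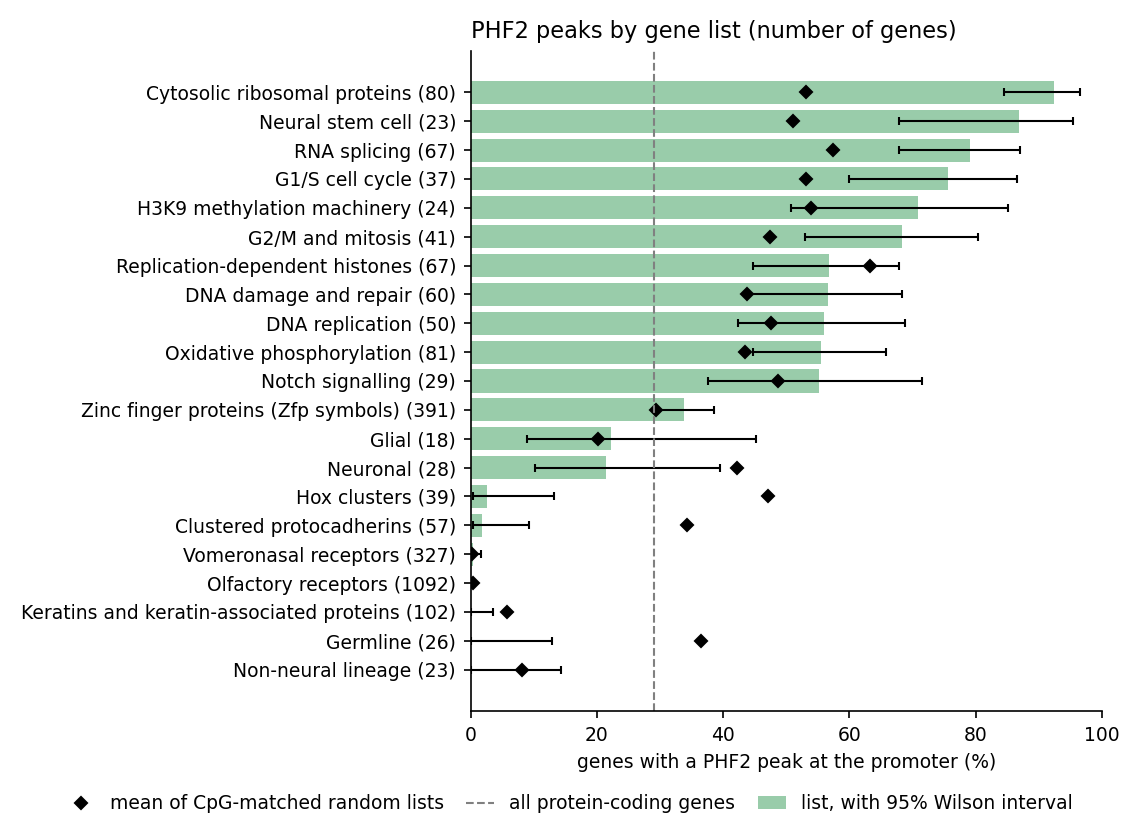
Share of genes of each list with a PHF2 peak at the promoter (%, bars with 95% Wilson intervals), with the mean of random lists matched on CpG content (diamonds) and the share of all protein-coding genes (dashed line, 29.1%). Ribosomal protein genes reached 92.5%, and Hox genes lay at 2.56%, far below their CpG-matched mean.

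Among the same lists, H3K9me2 singled out the olfactory receptor genes, which encode odorant receptors and are silent outside the olfactory epithelium. Of 1092 olfactory receptor genes, 79 (7.23%) had a region at the promoter, against 2.04% of other genes (odds ratio 3.75, 95% interval 2.93 to 4.81, Fisher's exact adjusted p = 1.6e-18). CpG-matched random lists held a mean of 33.3, a ratio of 2.37 (permutation adjusted p = 0.0042). With the 5'-most start alone the excess was smaller, 48 genes against a matched mean of 28.0 (permutation adjusted p = 0.0042). Both tests treat neighbouring genes as independent. The lists were not matched on the region of the genome. Olfr1262 (146 bp) came after the 3 receptor genes named above. No other list passed the threshold, and the 8 vomeronasal receptor genes of 327 (2.45%) with a region, Vmn1r85, Vmn1r230, Vmn1r236 and Vmn1r50 among them, gave an odds ratio of 1.07 (Fisher's exact adjusted p = 1). Regions lay at 6 of 391 zinc finger genes, Zfp804b, Zfp606, Zfp418 and Zfp119b among them, at 2 of 102 keratin genes (Krtap19-3 and Krtap21-1), at 2 of 28 neuronal genes (Elavl4 and Neurod1), and at 1 gene each of the DNA replication (Lig1), glial (Slc1a2) and non-neural (Ins2) lists. The other 13 lists had 0 genes with a region.

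PHF2 peaks were set apart from other promoter sequences of like GC content by several short motifs. Of the 12 motifs, 4 were more frequent and 3 less frequent in the central 200 bp of the 5992 peaks. The E2F consensus, the site of the cell cycle factors, occurred in 2.77% of peaks and 1.65% of control windows (odds ratio 1.70, Fisher's exact adjusted p = 0.000145). With controls also matched on the number of CpG dinucleotides, its odds ratio was 1.07 (Fisher's exact adjusted p = 0.667). The SOX consensus occurred in 4.37% of peaks and 3.35% of controls (odds ratio 1.32, Fisher's exact adjusted p = 0.00882), and with the CpG-matched controls its odds ratio was 1.45 (Fisher's exact adjusted p = 0.000712). In the central 100 bp, neither SOX (odds ratio 1.27, Fisher's exact adjusted p = 0.133) nor E2F (1.46, 0.059) passed the threshold. ETS (odds ratio 1.64) and ZBTB33 (3.29) were the other more frequent motifs, but with the CpG-matched controls ETS (odds ratio 1.33, Fisher's exact adjusted p = 0.0708) and ZBTB33 (2.56, adjusted p = 0.0503) did not pass the threshold. SP/KLF sites occurred in 5.82% of peaks against 12.8% of controls (odds ratio 0.422, Fisher's exact adjusted p = 7.45e-39), though over whole peaks the odds ratio was 0.937 (Fisher's exact adjusted p = 0.113). E-boxes occurred in 9.73% against 12.8%, and CTCF sites in 3 peaks against 24 controls. With the CpG-matched controls, E-boxes (Fisher's exact adjusted p = 0.0526) and CTCF sites (0.0503) did not pass the threshold either. NRF1, NFY, YY1, CREB/ATF and REST did not pass the threshold in the central 200 bp. With the CpG-matched controls NFY was less frequent (odds ratio 0.750, Fisher's exact adjusted p = 0.000712). Over whole peaks NRF1 (odds ratio 2.36, Fisher's exact adjusted p = 1.58e-30), YY1 (3.43, 2.3e-19), CREB/ATF (1.54, 1.01e-05) and NFY (1.23, 1.68e-07) were more frequent and REST less frequent (0.0907, 0.00759), and CTCF did not pass the threshold (0.893, 0.525). Against windows 1 kb to the side, SOX was less frequent (odds ratio 0.661) and SP/KLF more frequent (8.08).

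PHF2 peaks at promoters scored higher than the few elsewhere. The median of the authors' score was 230.27 for 5730 peaks at promoters and 196.36 for the 262 others, a difference of 33.9 (permutation p = 0.00436). With only the 5'-most start of each gene as promoter, the difference was 3.65 (permutation p = 0.568).

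The X chromosome was poor in peaks of both targets. PHF2 had 66 peaks on X where its length gave 383, a ratio of 0.172 (exact 95% interval 0.134 to 0.219, exact binomial p = 1.4e-92). Relative to the number of promoters, the ratio was 0.252 (exact 95% interval 0.195 to 0.320). H3K9me2 had 462 regions on X where its length gave 2307, a ratio of 0.200 (exact 95% interval 0.183 to 0.219). Among the autosomes, chromosome 11 had the highest PHF2 ratio by length, 1.70, and chromosome 14 the lowest, 0.777. Relative to the number of promoters, chromosome 11 was at 1.04 (exact binomial p = 0.328) and chromosome 14 at 0.890, while chromosome 12 was highest at 1.40 and chromosome 7 lowest of the autosomes at 0.614. The H3K9me2 ratios of the autosomes lay between 0.909, on chromosome 7, and 1.21.

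**Figure D4:**
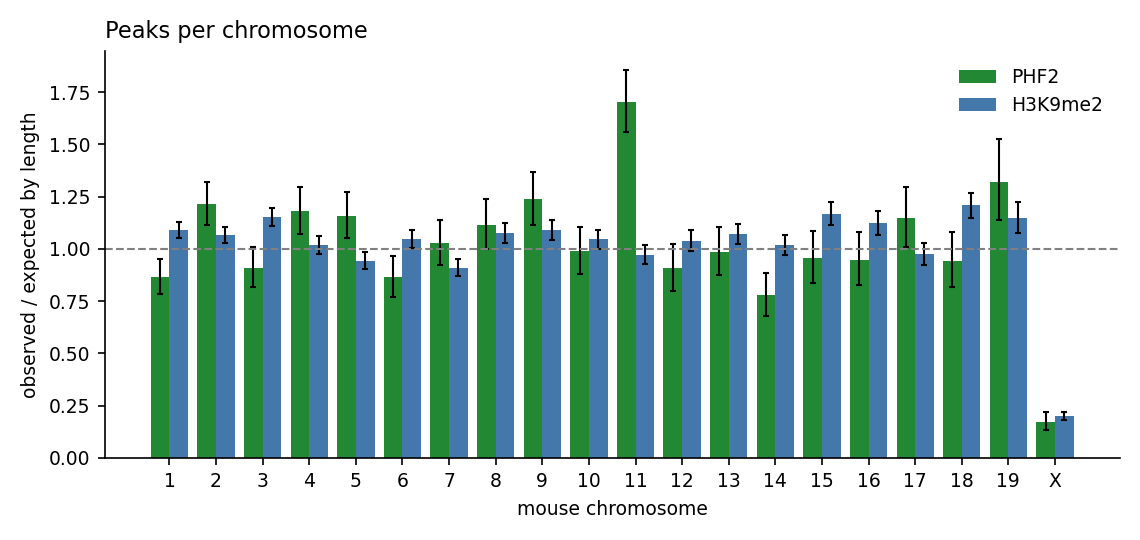
Number of peaks per mouse chromosome divided by the number its length outside gaps gives, for PHF2 (green) and H3K9me2 (blue), with exact 95% intervals. X lay lowest for both, at 0.172 and 0.200, and chromosome 11 highest for PHF2 by length, at 1.70, but at 1.04 relative to its number of promoters.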

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

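Of the tests in this part, those of CpG content, of repeats (under PHF2 peaks and on X), of PHF2 presence, of even scatter and of GC content with repeats were chosen only after the result was seen.

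Some H3K9me2 regions lay outside the chromosomes compared in the report. Of the 36171 regions listed, 60 lay on 15 unplaced or unlocalised scaffolds, and 34 of them on a single scaffold. The PHF2 list, of 5992 peaks, held 0 peaks on scaffolds, and a count of 0 allows up to 3. That limit takes no account of the sizes of the lists or the length of the scaffolds. These counts therefore show no difference between the targets and no excess on scaffolds. No explanation was tested for these regions.

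Few H3K9me2 regions lay under PHF2 peaks, with 3 overlaps where random placement gave 134. CpG content as the whole cause was argued against, though weakly. Intervals at transcript starts of the same CpG observed/expected without a PHF2 peak had a mean of 22.6 overlaps (12 to 35). The ratio was 0.133 (95% interval 0.0274 to 0.388), and that interval covers only the counting error of the 3 overlaps. The lowest of 10 CpG classes held 249 such starts with a region, and each other class 0 to 4. The matched mean thus rests on few starts outside the lowest class. Repeats as the whole cause were argued against by placements with at most 10% of soft-masked bases, which gave a ratio of 0.0199 (0.0041 to 0.0581). PHF2 presence, the only biological explanation tested, cannot be told apart from no effect. The odds ratio of single windows over CpG deciles was 0.979 (0.643 to 1.49), and windows differ in length and reach beyond the peaks. The depth of both samples, the fragmentation of open promoters and the calling of the regions stay open and were not tested.

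Both lists had few peaks on X. Repeats as the whole cause were argued against by H3K9me2 regions per unmasked Mb, which reached 0.237 of the autosomal value on X (95% interval 0.216 to 0.260). The number and CpG content of X promoters were argued against by 67 of 948 X genes with a PHF2 peak where autosomal genes of the same CpG decile gave 197, a ratio of 0.340 (0.265 to 0.427). A single X copy, as in male cells, may lower the score on X, where the median PHF2 score was lower by 58.3 (X minus autosomes -58.3; 171.27 against 229.57, permutation p = 0.0124), but it cannot be told apart from other causes: 58.6% of autosomal peaks had at least 2 times the lowest score, more than the ratio of 0.340 left on X, which goes against it if the score follows coverage, and the sex of the embryos and the scale of the score were not given in the sources used here. Neither list held a peak on Y. This does not settle the sex, since how Y was handled was not given in the sources used here. No biological explanation was tested.

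H3K9me2 regions were short and scattered. Even scatter by chance was argued against by a variance-to-mean ratio of 2.22 per bin of 1 Mb on autosomes, above the highest of 200 placements, 1.15. Dense domains split into short calls were argued against by the share of regions with another within 10 kb, which was 25.7% by placement and 1.17 times that in the list (95% interval 1.15 to 1.19), and within 1 kb 4.56% of regions had another against 3.17% by placement. GC content and repeats as the whole cause were argued against by a variance-to-mean ratio of 1.43 within classes of like bins, still above the highest placement, 1.15, although soft-masked bases made up 22.4% of regions and 33.6% of placements. Sparse domains wider than 10 kb, with which both ratios per bin go, the threshold of the calls and the depth stay open, and no biological explanation was tested.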

How the results depend on the processing

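The tests with the 5'-most start over CpG deciles, single windows, X left out, genes sharing a region counted once, placements low in repeats, and motif controls matched on CpG number were chosen only after the result was seen. The cause was not tested for any change below.

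Among the comparisons of main results with an alternative, 93 kept direction and side of the threshold or stayed within the bounds set for a count, 12 counts moved, 6 results weakened and 2 reversed. Those kept included every alternative for the share of PHF2 peaks and of H3K9me2 regions at promoters, for their overlap, for the density of H3K9me2 within 0.5 kb and from 10 to 20 kb, for the CpG difference, for X and for the number of H3K9me2 lists. The odds ratio of H3K9me2 at PHF2 promoters was 1.01 with windows of 5 kb and 0.982 with all annotated genes. It was 0.481 with the upper 10% of peaks, farther from 1 but from 7 of 616 genes (Fisher's exact p = 0.0545). When regions had to cover 10% of the window it was 0.487 from 0 and 2 genes, too few to tell. Over CpG deciles it was 1.67 for genes with all their windows pooled, whose number was not adjusted for. It was 0.901 with the 5'-most start and 0.979 for single windows. The score difference was 3.65 with the 5'-most start.

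The upper 10% of peaks by score left 4 lists higher and 2 lower for PHF2, and the odds ratio changed sides for DNA replication (0.337), G2/M (0.854), repair (0.579), oxidative phosphorylation (0.209), zinc finger (0.802) and neuronal genes (4.12), and for the ETS motif (0.331), with 1 motif higher and 1 lower. The upper 50% gave 0.842 for zinc finger genes and 1.03 for NFY. All annotated genes gave 1.60 for neuronal genes. CpG-matched lists left 7 higher, with ratios of 0.896 for histones and 1.43 for vomeronasal receptors. With the 5'-most start they left 6 higher and 3 lower, with 0.938 for histones.

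For motifs, the central 100 bp left 2 higher, with 0.961 for NRF1. Windows 1 kb to the side gave 8 higher and 1 lower, with 8.08 for SP/KLF, 3.17 for CREB/ATF, 0.661 for SOX and 1.22 for E-boxes. Whole peaks gave 8 higher, with 1.23 for NFY and 1.54 for CREB/ATF. Matching on CpG number left 1 higher, with 0.822 for NRF1. Among single lists, motifs and distance classes, 196 comparisons were the same, 50 weaker, 7 stronger and 21 reversed.

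Requiring that H3K9me2 cover a large part of a PHF2 peak gave no value, since no peak qualified. The lengths all but fixed this outcome, as regions had at most 367 bp and PHF2 peaks a median of 1306 bp. No paired analysis was possible because each group had 1 sample, and leaving out a replicate does not apply for the same reason. The unknown depth limits what a missing peak can show.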

Other observations

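The lists of ERK response genes and developmental transcription factors were made after the named genes and the Hox result had been seen, and of the tests in this part, the one on the wider list of these factors was chosen only after the result of the narrower list was seen.

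The high PHF2 scores at Spry2, Dusp6 and Myc led to the hypothesis that genes induced by ERK carry higher PHF2 scores. In a list of 29 such genes outside the 15 top-scoring ones, 21 had a PHF2 peak, where other genes of the same CpG deciles gave 16.0. The median score of those with a peak was 680.23 against 230.66 for other promoters with a peak. This was a difference of 449.6 (permutation p = 1e-05, the smallest possible), and the scores were not matched on CpG content. Jun (2146) and Phlda1 (1932) had the highest scores of the list. The cells were grown with EGF and FGF, which act through ERK, so activity of these genes in culture is a candidate explanation for the difference. Expression was not analysed here.

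The lack of PHF2 peaks at Hox genes led to the hypothesis that CpG-rich promoters of some other families of developmental transcription factors lack them too. The list held homeobox, forkhead, T-box, GATA and a few other families, and left out the Sox, Olig and Hes families, of which Olig2, Sox4, Sox11, Hes1 and Sox9 had high-scoring PHF2 peaks. Of its 147 genes, 22 had a PHF2 peak where CpG-matched random lists had a mean of 75.4 (65 to 86), a ratio of 0.292 (permutation p = 0.0002, the smallest possible). Since those families had been seen to hold peaks before the list was made, a wider list with the Sox, Olig, Hes and related families was tested: 48 of its 205 genes had a peak against a matched mean of 105.8 (94 to 118), a ratio of 0.454 (permutation p = 0.0002, the smallest possible). With the 5'-most start alone, 19 genes of the narrower list had a peak against a mean of 67.9 (permutation p = 0.0002, the smallest possible). The wider list contains the narrower one, so it is no independent check, and the added families were not tested by themselves. CpG content alone may not account for where PHF2 peaks lie in the narrower list, whose families were chosen with part of the result known. Neither expression nor other histone marks were analysed here.

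Divergent promoters, where starts of 2 protein-coding genes on opposite strands lie within 1 kb, held PHF2 peaks more often than others. A peak was present at 890 of 1536 such genes (57.9%), against 25.1% of other genes, and the odds ratio over CpG deciles was 1.63 (95% interval 1.45 to 1.84, permutation p = 0.0002, the smallest possible). Both genes of such a pair were counted as separate genes, although the same peak can lie at both. The interval and the permutation p ignore this pairing, so they are likely too narrow and too small. A shared promoter may be bound for either gene, which the ratio of 1.63 alone does not tell apart from a property of these promoters.

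Across bins of 1 Mb on autosomes, both targets ran in opposite directions with GC content. From the lowest to the highest of 4 classes of GC content, H3K9me2 regions per Mb were 17.1, 17.2, 15.3 and 10.5. In the same order, PHF2 peaks per Mb were 0.376, 1.59, 2.98 and 4.85. Genes per Mb rose as well, at 2.59, 6.16, 8.65 and 16.5. Since nearly all PHF2 peaks lay at promoters, their rise with GC content was not told apart from the number of genes.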
